A study of Mus musculus with 15 samples.

How the data were processed

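ATAC-seq libraries of mouse bone marrow-derived macrophages were given as 15 peak lists, 3 for untreated cells and 3 for each of 4 LPS times (30 min, 1 h, 2 h and 4 h at 10 ng/ml). The submitters' processing notes name Bowtie 1.1.2, MACS 1.4 and the mouse genome build mm9. Settings of the aligner and the caller, the treatment of duplicates, the shift of reads for the transposase, a control library and a blacklist of problem regions are not given in the sources used here. The authors deposited 1 list per library, and the lists share almost no identical intervals, so peaks were called for each library separately. A list without a header gives each peak's chromosome, start, end, name and a score. The deposited score is the peak caller's own value, by its range and the caller's usual output 10 times the −log10 of the peak's p-value, which no header states. It ran from 50 to 3233.06, with 5.0% of all peaks tied at 3100. A score belongs to its own list and was used to rank and filter peaks within that list. The exception is the choice of regions to name, which ranks them by the lowest score among 3 lists, so that order is no measure of the size of a change. No read counts came with the lists, so depth is unknown, and peak number may follow depth. A region without a peak may be accessible below the caller's threshold. A longer list holds more weak regions in every comparison it enters.

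Groups and replicate numbers were taken from the sample titles. All intervals are printed with the first base counted as 1. The 2 mitochondrial peaks of each list were left out of the regions, since they are not chromatin. No 2 lists held more than 13 identical intervals, so each counted as its own library. Peaks of all 15 lists that overlapped by 1 bp or more were merged into regions, and a library was scored as having a peak in a region or not. Gained regions had a peak in 3 of 3 libraries at an LPS time and in 0 of 3 untreated libraries, and lost regions the reverse. Counts were compared with the number expected if labels were exchangeable (regions with a peak in exactly 3 of the 6 libraries, divided by 20), with other splits of the libraries, and with 100 simulated sets in which every region kept its frequency over the 15 libraries and every library its list length. The simulated frequencies contain any real effect of LPS, which makes them a rough reference.

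Over the 15 libraries, regions with a peak in 3 to 12 libraries were tested with Fisher's exact test (12 LPS against 3 untreated, smallest two-sided p 0.0022) and with an exact trend test on the order of the times, both two-sided and adjusted by Benjamini and Hochberg at 0.05. Numbers and widths of peaks were compared with exact two-sided permutation tests of the difference in means. Similarity of peak sets was the Jaccard index in base pairs, tested with 100000 relabellings, one-sided. Peaks of 10 kb or more were counted per library, and a region was called broad in a library that had such a peak in it. Regions are named by position under a rule set before the data were examined: per time and direction, the 5 regions whose lowest score among the 3 libraries with a peak was highest. Broad regions were named after the data had been seen, by a like rule on width: the 5 with the largest lowest width per time, and all that lost a broad peak.

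On simulated lists modelled on the comparison of 2 h with untreated cells, with 104855 regions of which 2000 opened and 2000 closed (chance of a peak 0.95 against 0.05), the rule recovered 73.52% of opened and 73.81% of closed regions. Of the gained calls 42.68% were regions that had not been changed, and of the lost calls 3.64%, which reflects the longer lists at 2 h. Fisher's exact test with adjustment recovered 46.4% of the opened regions, with 0.52% false calls. The simulated regions changed at all LPS times, while the data held 307 gained and 98 lost at all 4 times. That recovery therefore does not carry over to the data. The trend test recovered 0% of the opened regions, since a single step between untreated and treated does not reach its threshold.

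The numbering of replicates was checked as a pairing. Deviations of same-numbered untreated and LPS libraries from their group means correlated at 0.031 to 0.27 across regions. Same-numbered LPS libraries of different times were not compared in this way. Not all exceeded 0.1, so the numbers were not treated as pairs in the main tests. All were positive, so an effect shared by replicate number stays possible. Alternatives were a stricter score of 100, lists cut to equal length by score, coverage of 50% of a region, bins of 500 bp, a relaxed and a sharper rule of presence, each library left out in turn, and blocking by replicate number. Planned analyses of gene lists, cell type markers, position relative to genes and sequence motifs need a genome and annotation of build mm9. The gene table at hand is of the assembly GRCm38 and coordinates were not converted between builds, so these were not analysed here and no gene is named. Values per library were also compared between the 4 LPS times with an exact permutation test over all 15400 ways of forming 4 groups of 3, and the spacing of changed regions and their share per chromosome were described, all after the data had been examined. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.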

Results

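Chromatin accessibility was profiled by ATAC-seq, which reads out the DNA that a transposase can reach, in primary macrophages grown from mouse bone marrow (C57BL/6 strain) and collected on day 7 of differentiation. The cells were left untreated or received bacterial lipopolysaccharide (LPS, an activator of the innate receptor TLR4) at 10 ng/ml for 30 min, 1 h, 2 h or 4 h. Each of the 5 groups held 3 libraries, and each of the 15 libraries had its own peak list on mouse genome build mm9. The lists held 52449 to 82224 peaks. The number of sequenced reads behind them is unknown, so no counting interval can be given and a missing peak means only that none was called. The labels call the libraries triplicates without saying whether they came from separate mice or cultures, so p-values of comparisons between libraries measure the spread between these libraries, which may be technical. No annotation of build mm9 was used here. Regions are therefore identified by position, and the gene, exon or intron they lie in is not given.

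Overlapping peaks of the 15 lists merged into 104855 regions on the nuclear chromosomes, with a median width of 1647 bp. Of these, 34777 regions (33.2%) carried a peak in all 15 libraries, untreated and LPS-treated alike. A further 15875 carried a peak in 1 library only. The remaining regions include 36919 with a peak in 3 to 12 libraries, the ones in which a group of 3 could differ completely from another.

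The first question was how far the accessible genome as a whole moved with LPS. Peak sets of the same time point shared more of their covered bases (mean Jaccard index 0.648) than peak sets of different time points (0.607), and the difference of 0.0408 exceeded that of nearly all relabellings (permutation p = 0.00063, one-sided, 100000 resamples). Untreated libraries resembled those at 30 min (0.629) almost as much as they resembled each other (0.639). Their similarity to the libraries at 1 h, 2 h and 4 h was 0.571, 0.574 and 0.573. The 2 h libraries were the closest to one another (0.698), and they lay nearer to the 4 h libraries (0.654) than to the untreated ones. The excess within time points was not seen at each time. The 1 h libraries resembled each other less (0.616) than they resembled those at 30 min (0.628) and 2 h (0.626). Likewise, the 4 h libraries resembled each other less (0.645) than they resembled those at 2 h (0.654). Libraries with the same replicate number were also more alike (0.628 against 0.607, permutation p = 0.023), and with all lists cut to the same length that excess was 0.00702 (permutation p = 0.17), while the one for time points was 0.056 (permutation p = 1e-05, the smallest the resamples can give).

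**Figure D1:**
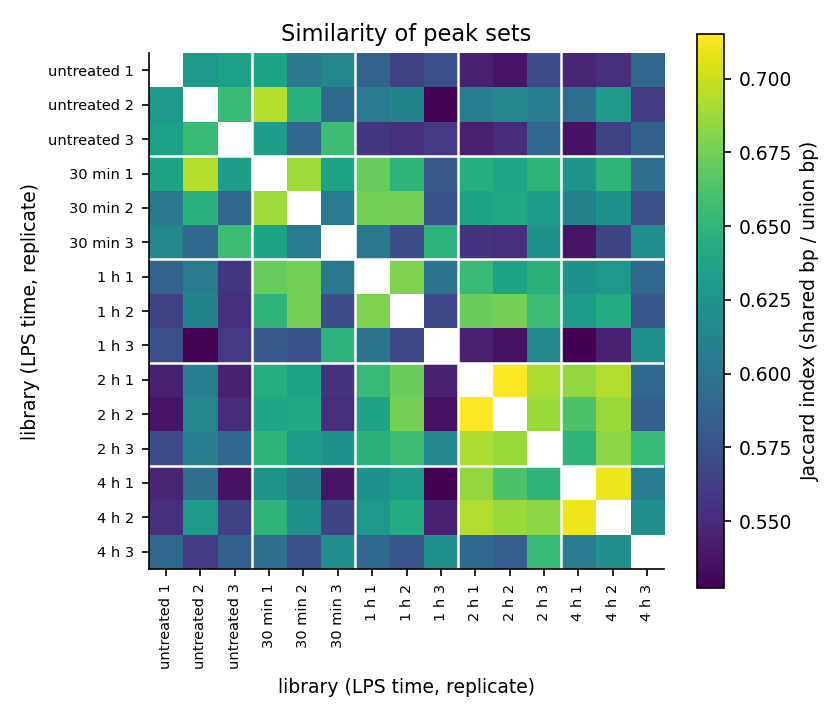
Pairwise similarity of the 15 peak sets, as the Jaccard index (bases shared by both sets over bases in either), libraries ordered by LPS time and replicate, with white lines between time points and the diagonal left blank. The block of 2 h libraries is brightest (mean 0.698), and untreated libraries are closer to those at 30 min (0.629) than to those at 4 h (0.573).

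The number of peaks did not differ detectably with LPS. Untreated libraries had 65277 ± 7203 nuclear peaks (SD, n = 3), libraries at 2 h had 76692 ± 8458 (SD, n = 3), and no time point differed from untreated in an exact two-sided permutation test (p = 0.2 at 2 h, 0.6 at 4 h, 0.9 at 30 min and at 1 h). With 3 libraries against 3 that test cannot give a p below 0.1. The 12 LPS libraries together had 1.08 times as many peaks as the untreated ones (exact two-sided permutation p = 0.453). Covered length was 100.6 ± 17.7 Mb in untreated libraries and 122.1 ± 8.33 Mb at 2 h (SD, n = 3, exact permutation p = 0.2). Replicate 3 had the shortest list at each LPS time, between 52449 peaks at 1 h and 66957 at 2 h.

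The next question was which regions opened or closed at each time. A region was called gained at a time point if it carried a peak in 3 of 3 LPS libraries and 0 of 3 untreated ones, and lost in the reverse case. For a single region this contrast cannot pass a test, since Fisher's exact test of 3 against 3 gives 0.1 at best, so the counts were set against simulated unchanged groups that kept each library's list length. If library labels were exchangeable, 330.7, 415.8, 518.0 and 457.9 regions would be expected in each direction at the 4 times.

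After 30 min, 786 regions were gained and 290 were lost. In simulated unchanged groups 318.7 ± 19.8 were gained and 216 ± 14 were lost (mean ± SD of 100 draws). The gained count was 2.47 times and the lost count 1.34 times the simulated one, and the lost count lay below the 330.7 expected from exchangeable labels. Of the 10 splits of these 6 libraries into 3 and 3, 2 reached the real count of 1076 changed regions, the real split among them. The highest other gave 2419, so the excess at 30 min is not set apart from differences between libraries. The highest-ranked gains (by the lowest score among the 3 libraries, a rule that only picks which regions to name) were on chromosome 3 at 36351135 to 36355512, chromosome 13 at 37597184 to 37599027, chromosome 10 at 18749965 to 18751855 and chromosome 2 at 140671822 to 140674566. All of these kept a peak in every LPS library to 4 h. The fifth, on chromosome 10 at 82815945 to 82817787, had a peak in 9 of 9 libraries to 2 h and in 1 of 3 at 4 h. The highest-ranked loss, on chromosome 5 at 65831210 to 65833212, was temporary: peaks were called in 3 untreated libraries, none at 30 min, 1 at 1 h, 2 at 2 h and 3 at 4 h. The losses on chromosome 3 at 80849898 to 80851739 and chromosome 14 at 73797464 to 73799231 had likewise returned in 3 of 3 libraries at 2 h and at 4 h. Others stayed away: the loss on chromosome 16 at 12060875 to 12062854 had a peak in 1 of the 9 later libraries, and the one on chromosome 16 at 7371137 to 7372500 in none. Leaving out a library loosens the rule, and the gained count became 2839 without 30 min replicate 3 and 1506 without untreated replicate 2. The lost count became 1515 without untreated replicate 1, more than the 843 then gained, and it was 646 without untreated replicate 3, 781 without 30 min replicate 1 and 639 without 30 min replicate 2.

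After 1 h, 1756 regions were gained and 1259 were lost, 6.89 and 5.68 times the simulated unchanged counts of 255 and 222. The simulated libraries vary independently, which real libraries need not do. Against the 415.8 expected from exchangeable labels the gained count was 4.22 times and the lost count 3.03 times as high. Another split of these 6 libraries gave 2037 changed regions, against 3015 for the real one. The region on chromosome 3 at 36351135 to 36355512 again ranked first among the gains. It was followed by regions on chromosome 4 at 134861815 to 134867281, chromosome 2 at 140671822 to 140674566, chromosome 4 at 117820688 to 117823006 and chromosome 7 at 108361410 to 108363630. Each of these 5 was free of peaks in untreated libraries and had one in all 12 LPS libraries. The highest-ranked loss, on chromosome 4 at 19782505 to 19784385, had a peak in 6 of 6 untreated and 30 min libraries and in none of the 9 later ones, and the loss on chromosome 13 at 113222837 to 113224496 followed the same course. The losses on chromosome 3 at 87058840 to 87060277, on chromosome 3 at 60936434 to 60938089 and on chromosome 6 at 82754298 to 82756125 had a peak in 2 of 3 libraries again at 4 h. The gained count became 5626 without 1 h replicate 3 and 2683 without untreated replicate 2, and the lost count became 3275 without untreated replicate 1 and 2602 without 1 h replicate 2. Both exceed the gained counts without those libraries, 1847 and 1852.

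After 2 h, 5272 regions were gained, the highest count of the 4 times, and 857 were lost. Simulated unchanged groups gave 1232 ± 36.8 gained and 57.2 ± 7.9 lost (mean ± SD), so that the list lengths alone already favoured gains here. The gained count was 4.28 times and the lost count 15 times the simulated one. Against the 518.0 expected from exchangeable labels the gained count was 10.2 times and the lost count 1.65 times as high. With labels swapped only within replicate numbers, gains were 6.18 times and losses 1.01 times the expected count. The regions on chromosome 4 at 117820688 to 117823006 and chromosome 7 at 81671686 to 81675861 had a score of 3100 as the lowest among the 3 libraries, a value at which many peaks are tied. Those on chromosome 18 at 11885813 to 11887583 and chromosome 12 at 56465386 to 56467418 had a peak in 2 of 3 libraries at 30 min and in every library from 1 h on. Gained peaks were mostly not the strongest of their list: their median score stood at percentile 27.0 to 40.3 of the 3 lists. The highest-ranked loss, on chromosome 6 at 122529117 to 122538569, was wide (9453 bp). It had a peak in 3 of 3 libraries untreated and at 30 min, in 1 at 1 h, in none at 2 h and in 3 at 4 h. The peaks at 4 h scored 161.07 to 265.86 in their lists, against 1624.85 to 3100 in the untreated lists, so a full return is not shown. The losses on chromosome 4 at 19782505 to 19784385 and on chromosome 3 at 60936434 to 60938089 were those already seen at 1 h. With every list cut to the length of the shortest, gained regions numbered 3410 and lost regions 2111, and the share of gains among changed regions was 61.8% in place of 86.0%. The gained count became 9307 without 2 h replicate 3, and the lost count became 2333 without untreated replicate 1, 1407 without untreated replicate 3 and 1442 without 2 h replicate 2.

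After 4 h, 2928 regions were gained and 1119 were lost, 6.2 and 9.4 times the simulated unchanged counts of 472.3 and 119. Against the 457.9 expected from exchangeable labels the gained count was 6.4 times and the lost count 2.44 times as high. Another split of these 6 libraries gave 2335 changed regions, against 4047 for the real one. The region on chromosome 7 at 81671686 to 81675861 ranked first among the gains, followed by regions on chromosome 1 at 152043838 to 152046149, chromosome 1 at 175959128 to 175963158, chromosome 18 at 11885813 to 11887583 and chromosome 6 at 15632350 to 15634657. All 5 had a peak in every library from 1 h on. The highest-ranked loss was again that on chromosome 4 at 19782505 to 19784385. Others were complete only at 4 h: the region on chromosome 10 at 87366325 to 87372673 still had a peak in 3 of 3 libraries at 1 h and in 2 of 3 at 2 h, and that on chromosome 9 at 78426028 to 78427760 in 2 of 3 at both times. The one on chromosome 3 at 27099512 to 27103953 had a peak in 1 of 3 libraries at 1 h and in 2 of 3 at 2 h. With lists of equal length the share of gains among changed regions was 59.5% in place of 72.3%, and it was 63.8% in place of 73.0% at 30 min and 53.2% in place of 58.2% at 1 h. The gained count became 8139 without 4 h replicate 3. The lost count became 3089 without untreated replicate 1, 1714 without untreated replicate 3, 1803 without 4 h replicate 1 and 1736 without 4 h replicate 2.

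**Figure D2:**
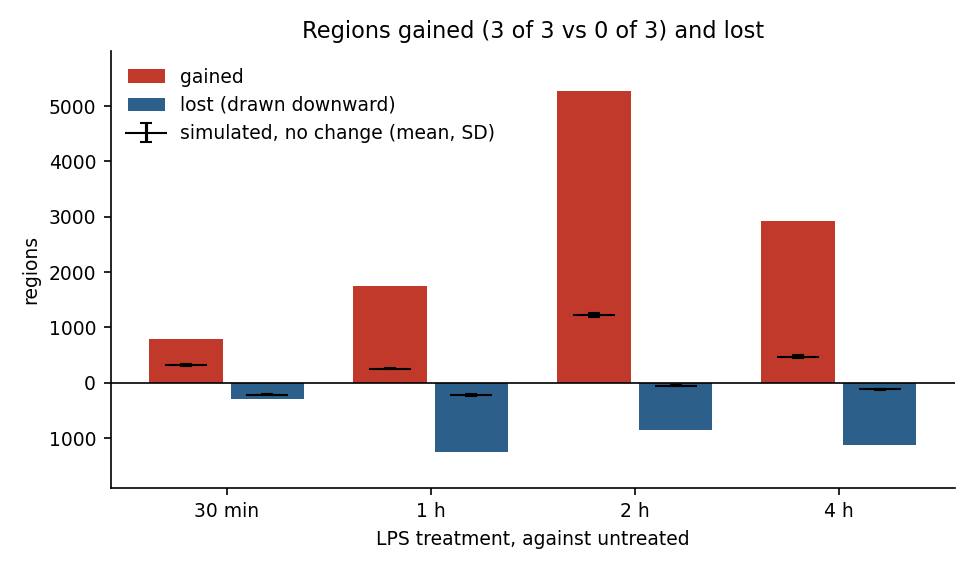
Regions gained (upward, red) and lost (downward, blue) at each LPS time against untreated libraries, with black marks for the mean and SD of 100 simulated unchanged groups. Gains rise from 786 at 30 min to 5272 at 2 h and stand at 2928 at 4 h, and each bar lies beyond its simulated value. The SD covers only the draws, in which libraries vary independently. At 30 min another split of the same 6 libraries gave more changed regions than the real one.

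Over the time course, 6487 regions were gained at 1 or more times and 2073 were lost. Gains were first complete in 3 of 3 libraries at 2 h in 56.5% of these regions, at 1 h in 18.8%, at 4 h in 12.7% and at 30 min in 12.1%. These shares depended on list length: with lists of equal length, an alternative chosen after seeing the data, they were 34.6% at 2 h and 29.8% at 1 h. Of the losses, 51.1% were first complete at 1 h, and 44.7% with lists of equal length. Only 307 regions were gained at all 4 times and 98 were lost at all 4. Of the regions gained at 2 h, 39.7% had a peak in 3 of 3 libraries at 4 h and 14.2% had none. The 4 h libraries differed in this: 79.8% of the regions gained at 2 h had a peak in replicate 1, 73.3% in replicate 2 and 43.7% in replicate 3, and 68.5% had one in replicates 1 and 2 together. Of the regions lost at 1 h, 43.2% had no peak in any 4 h library and 10.7% had one in all 3.

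The overlap between times does not separate a shared response from the shared untreated libraries. Gains at 2 h and 4 h shared 2092 regions, 5.0 times the 418 expected for independent lists of these sizes. In simulated unchanged groups, whose lists were shorter, 139 ± 11 were shared (mean ± SD), 9.93 times the expectation for their own sizes, a comparison added after seeing the data. Gains at 1 h and 2 h shared 1503 (5.99 times, simulated 11.3 times), those at 30 min and 4 h 355 (5.69 and 15 times), and losses at 1 h and 4 h 544 (14.3 and 34.4 times). Such a ratio cannot exceed the 36919 regions with a peak in 3 to 12 libraries, divided by the length of the longer list. The real lists, being longer, could not reach the simulated ratios given here, so their lower ratios decide nothing. All comparisons used the same 3 untreated libraries, which are too few to be split. How much of the excess over independent lists comes from the shared controls is therefore not known.

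Single regions were tested over all 15 libraries. With Fisher's exact test of the 12 LPS against the 3 untreated libraries, 0 of the 36919 regions passed an adjusted p of 0.05 (Benjamini-Hochberg, smallest adjusted p = 0.2), while 2100 were more often open and 853 less often open with LPS at an unadjusted p under 0.05. No p of this test can lie below 0.0022, so regions pass the adjustment only where very many separate completely. Here 307 gained and 98 lost regions did, so 0 calls do not show that no region changed. An exact trend test over the ordered times called 785 regions that were open more often with time and 74 that were open less often (Benjamini-Hochberg adjusted p under 0.05, smallest 0.0399). With lists of equal length it called 2416 and 1364 among 24163 regions tested. At an unadjusted exact p under 0.05 the rising regions then fell from 6160 to 4281, and the falling ones rose from 2012 to 3484. The balance thus moved with list length, while the larger adjusted counts may also follow from fewer tests. The trend counts also rested on single libraries. Leaving out untreated replicates 1, 2 or 3 gave 265, 276 and 348 rising regions, and leaving out 30 min replicates 1, 2 or 3 gave 1449, 1933 and 340. Without 1 h replicate 1 or without 4 h replicate 1 no region passed in either direction. The other counts of rising regions were 555 and 496 without 1 h replicates 2 and 3, 357, 369 and 446 without 2 h replicates 1, 2 and 3, and 354 and 2627 without 4 h replicates 2 and 3. The count of falling regions ranged from 0 to 401, the latter without 30 min replicate 2. With 1 to 14 libraries allowed per region no region passed (smallest adjusted p = 0.0757), while 6160 were open more often with time and 2012 less often at an unadjusted exact p under 0.05. With replicate numbers as blocks the exact trend test called no region either (smallest Benjamini-Hochberg adjusted p = 0.086).

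LPS libraries also differed in the number of peaks called over 10 kb or more. This comparison and its width were chosen after the widths of the peaks had been seen. Untreated libraries had 24.7 ± 10.8 peaks of 10 kb or more (SD, n = 3), and the number was 68.3 ± 13.6 at 30 min, 74.7 ± 24.2 at 1 h and 83.7 ± 5.13 at 2 h (SD, n = 3 each). The 4 h libraries had 89, 106 and 45. All 12 LPS libraries lay above all 3 untreated ones, 3.11 times as many on average (exact two-sided permutation p = 0.0022, adjusted p = 0.011 over the 5 comparisons). Each single time point reached the smallest p possible, 0.1. The median peak width hardly moved, from 1371 ± 100.2 bp untreated to 1398 ± 77.0 bp at 2 h (SD, n = 3, exact permutation p = 0.8). For peaks of 5 kb or more the ratio was 1.38 (exact permutation p = 0.242), and with neighbouring peaks within 1 kb joined first it was 1.79 (exact permutation p = 0.0527).

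**Figure D3:**
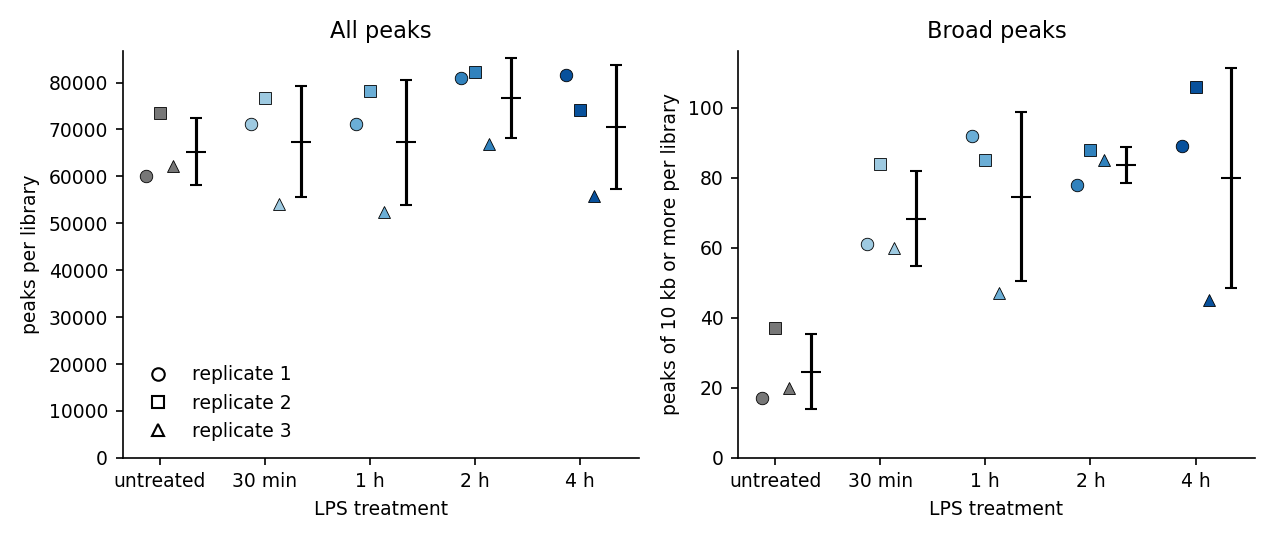
Number of peaks (left) and of peaks of 10 kb or more (right) in each library by LPS time, with marker shapes for replicate numbers and black bars for the group mean and SD (n = 3). Peak numbers overlap between groups, while the 12 LPS libraries have 45 to 106 broad peaks and the untreated libraries 17 to 37.

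Regions that had a peak of 10 kb or more in 3 of 3 LPS libraries and in 0 of 3 untreated ones numbered 15 at 30 min, 26 at 1 h, 43 at 2 h and 23 at 4 h, and the reverse case numbered 1, 2, 2 and 2. If library labels were exchangeable 1, 1.6, 2.45 and 1.7 would be expected in each direction. These counts rise when a library is left out, to 28 without 30 min replicate 1, 41 without 1 h replicate 3 and 47 without 4 h replicate 3, and the lost ones to at most 6, without untreated replicate 1 or 3. The gained broad regions all held narrower peaks in 3 of 3 untreated libraries, so none of them was among the gained regions described above. The 63 different broad regions fell into 14 that were broad in 3 of 3 libraries only at 30 min or 1 h, 31 only at 2 h or 4 h and 18 at both early and late times. Only 2 were broad in 3 of 3 libraries at all 4 times. Some of the 63 are direct neighbours across a short gap and may belong to 1 stretch. On chromosome 4, the region at 144797660 to 144822415 was broad early and late, and its neighbour at 144822522 to 144838428 only late.

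The early regions are by definition those not broad in 3 of 3 libraries at 2 h or at 4 h, so a fall after 1 h partly follows from the grouping. On chromosome 5 at 99639428 to 99684794 the widest peak measured 3.93 ± 1.49 kb untreated, 40.8 ± 4.9 kb at 30 min, 40.2 ± 4.56 kb at 1 h and 5.65 ± 1.36 kb at 2 h (SD, n = 3 each). Peaks still covered 62.5% of that region at 2 h, against 27.6% untreated, so a narrower widest peak is not a full return. On chromosome 12 at 86938279 to 86990735 the widest peak reached 49.3 ± 2.35 kb at 1 h, from 2.79 ± 0.245 kb untreated, and was 3.95 ± 0.429 kb at 2 h. Peaks then covered 52.7% of the region, against 19.1% untreated. On chromosome 13 at 43879338 to 43909799 the widest peak was 27.8 ± 1.95 kb at 1 h and 3.88 ± 0.103 kb at 2 h. On chromosome 5 at 139228679 to 139293867 it was 43.3 ± 12.6 kb at 30 min, 27.1 ± 22.9 kb at 1 h and 5.91 ± 2.57 kb at 2 h. The region on chromosome 11 at 16864644 to 16909929, broad at early times and at 2 h, narrowed more slowly: its widest peak was 42 ± 3.12 kb at 30 min, 44.1 ± 1.2 kb at 1 h, 28.9 ± 13.4 kb at 2 h and 8.54 ± 0.379 kb at 4 h. Peaks still covered 79.3% of it at 4 h, against 30.5% untreated. Also broad at early times and at 2 h were chromosome 2 at 164238792 to 164271057 and chromosome 12 at 112678506 to 112698686. Their widest peaks still measured 26.7 ± 0.195 kb and 19.8 ± 0.0877 kb at 2 h, and 15.1 ± 10.1 kb and 9.44 ± 2.74 kb at 4 h. Among the 14 early regions, the median share of the region covered by peaks was 33.2% untreated, 91.0% at 1 h, 71.1% at 2 h and 42.6% at 4 h. Of these regions, 11 had no broad peak in any 4 h library.

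As a class, the 31 regions broad only late were covered more by peaks already before 2 h, with a median of 24.4% untreated, 50.1% at 30 min, 64.2% at 1 h and 94.7% at 2 h. The named ones had no peak of 10 kb in any library at 30 min or 1 h. Others of the class had one in 1 or 2 of 3 libraries at 30 min, at 1 h or at both. The region on chromosome 11 at 86388767 to 86402151 had one in 2 of 3 libraries at 30 min and in none at 1 h. In the widest, on chromosome 11 at 119258997 to 119358168, the widest peak measured 2.62 ± 1.32 kb untreated, 2.42 ± 0.649 kb at 30 min and 2.2 ± 0.712 kb at 1 h, then 85.6 ± 16.3 kb at 2 h and 69.8 ± 2.54 kb at 4 h (SD, n = 3 each). Peaks covered 12.7% of it at 1 h and 96.5% at 2 h. The region on chromosome 12 at 27122328 to 27142352 went from 1.82 ± 0.0843 kb at 1 h to 18.9 ± 0.164 kb at 2 h and 19.3 ± 0.6 kb at 4 h, and its neighbour at 27152797 to 27171614 was 18 ± 0.436 kb at 4 h. On chromosome 11 at 78732481 to 78783487 the widest peak was 1.31 ± 0.143 kb untreated, 4.22 ± 0.951 kb at 2 h and 34.1 ± 15.9 kb at 4 h. On chromosome 2 at 90288387 to 90347343 a broad peak was present at 2 h only, at 42 ± 7.17 kb, against 6.65 ± 2.44 kb at 1 h and 7.63 ± 1.15 kb at 4 h. Of the 2 regions broad at all 4 times, the named one lay on chromosome 1 at 132962472 to 132995390, where the widest peak was 4.12 ± 0.0811 kb untreated and 20.6 ± 11.3, 23.7 ± 11.3, 29.2 ± 3.03 and 12.9 ± 3.52 kb at the 4 times. Its neighbour at 132931723 to 132962352 was broad in 3 of 3 libraries from 1 h on, with a widest peak of 28.3 ± 0.0881 kb at 2 h. The 3 regions that lost a broad peak were on chromosome 11 at 120484901 to 120496029, chromosome 7 at 149557296 to 149581759 and chromosome 19 at 3901363 to 3915717. The one on chromosome 7 narrowed from a mean of 17.9 kb untreated to 5.66 kb at 1 h and 6.22 kb at 4 h, while the one on chromosome 19 went from 12.5 kb to 6.67 kb at 1 h and 12.2 kb at 4 h.

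**Figure D4:**
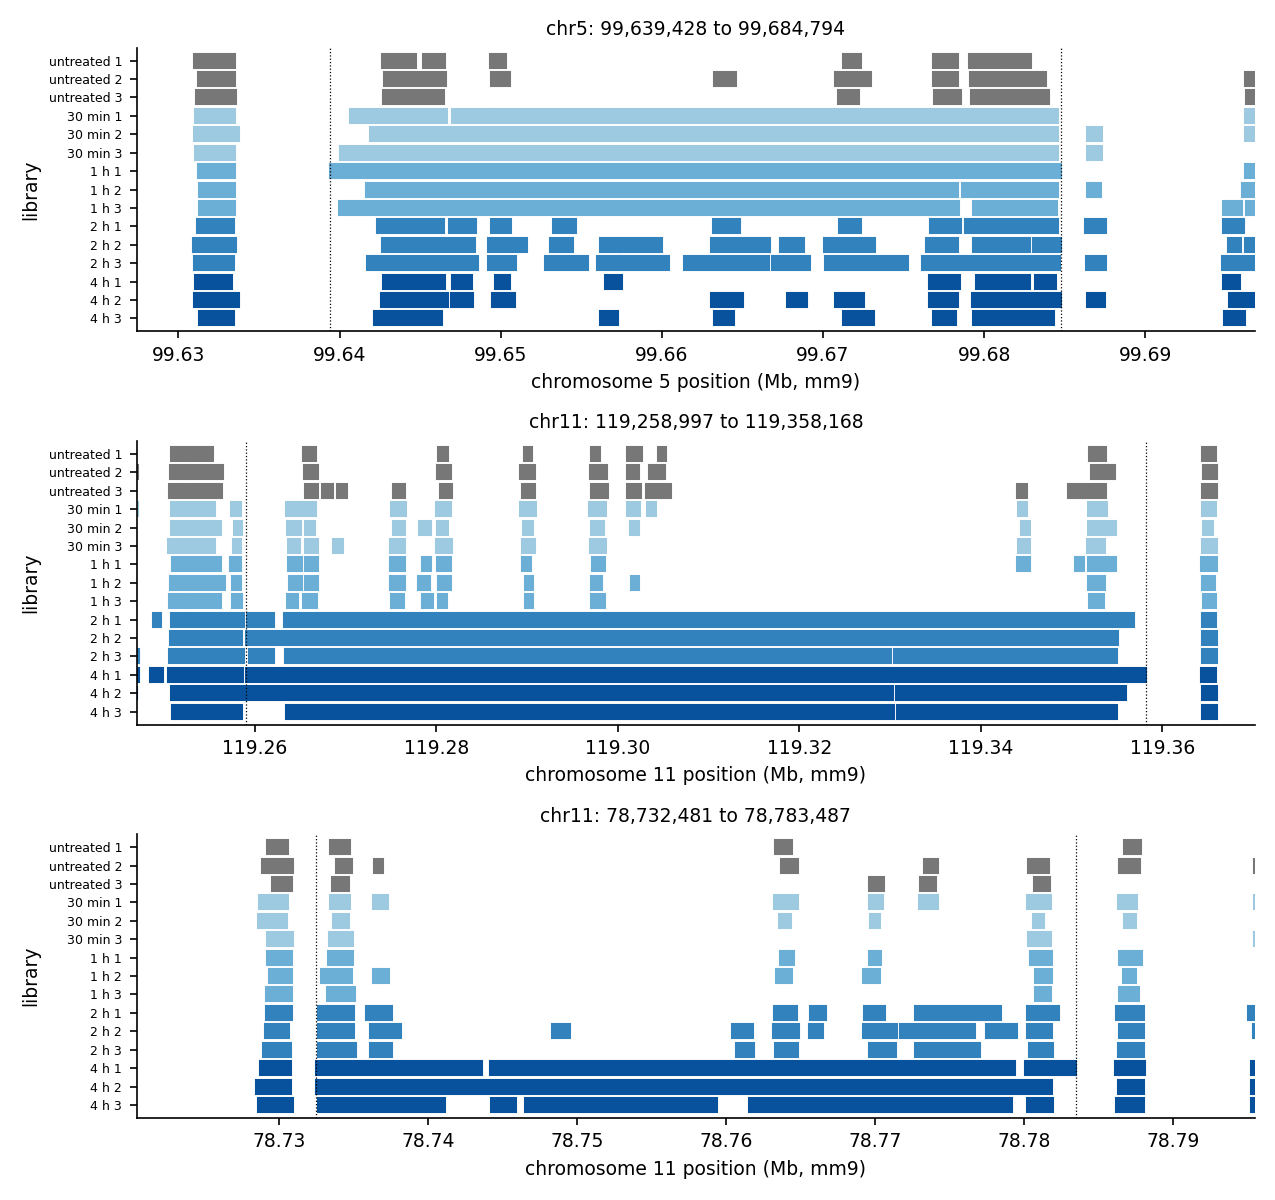
Peaks called in each of the 15 libraries (rows, coloured by LPS time) along 3 broad regions, with position in Mb on build mm9 and dotted lines at the region's ends. Coverage with few gaps appears at 30 min and 1 h on chromosome 5 (top), at 2 h and 4 h on chromosome 11 at 119258997 to 119358168 (middle), and at 4 h on chromosome 11 at 78732481 to 78783487 (bottom), 3 of the named broad regions, picked after the data had been seen to show different times.

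**Figure D5:**
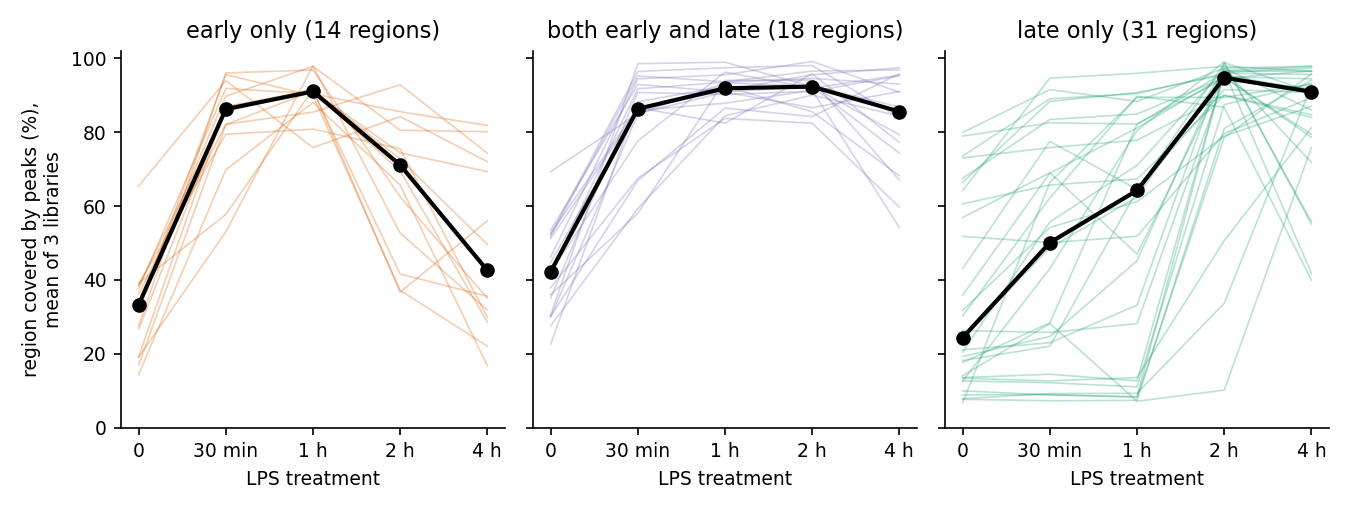
Share of each of the 63 broad regions covered by peaks (percent, mean of 3 libraries, thin lines) and the median (black) by LPS time, for regions broad only early, at both early and late times, and only late. The classes were set from the same libraries, so their peak times follow from the grouping, and the median of the early class falls from 91.0% at 1 h to 42.6% at 4 h.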

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

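The tests between LPS times were chosen after the results had been seen. Of 7 values per library compared between the 4 LPS times, 2 differed at an unadjusted exact permutation p under 0.05, and neither did after Benjamini-Hochberg adjustment (adjusted p = 0.0875 for both). Groups of 3 libraries are too small to test for a single library apart from the others.

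The similarity of a library to the untreated ones differed between LPS times (exact permutation p = 0.0175). Its mean Jaccard index was 0.629 ± 0.0219 at 30 min, 0.571 ± 0.0155 at 1 h, 0.574 ± 0.0132 at 2 h and 0.573 ± 0.0119 at 4 h (SD, n = 3 each). The width of the widest peak also differed between LPS times (exact permutation p = 0.025). It was 51.2, 51.0 and 75.4 kb in the 30 min libraries, 71.6 ± 1.87 kb at 1 h, 87.8 ± 12.3 kb at 2 h and 72.9 ± 1.38 kb at 4 h, against 37.3 ± 12.1 kb in untreated libraries (SD, n = 3 each, the latter not part of the test). This value rests on 1 peak per library.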

How the results depend on the processing

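The alternatives for broad peaks and for the course of gained and lost regions were chosen after seeing the data. Gains and losses kept their order (more gained than lost at each time) with stricter scores, equal list lengths, 500 bp bins and 50% coverage of the region, while the counts moved with the rule. The order turned at 30 min without untreated replicate 1 (843 gained, 1515 lost) and at 1 h without untreated replicate 1 (1847 gained, 3275 lost) or 1 h replicate 2 (1852 gained, 2602 lost). The cause of the shifts was not tested, except that looser rules and fewer libraries raise counts by construction. With a peak in 2 or 3 of 3 libraries against none, gains were 3244, 5917, 10465 and 8637 at the 4 times and losses 1969, 4070, 3027 and 3845. With a score of 100 or more against no peak, gains were 248, 733, 2561 and 1309 and losses 14, 247, 173 and 203. In 500 bp bins, gains at 30 min were 1386 and losses were 1035, 2074, 2058 and 2052. With equal list length, gains at 2 h were 3410, and losses at 30 min, 2 h and 4 h were 478, 2111 and 1925. Of the regions gained at 30 min and 2 h, 50.3% and 53.5% then had a peak in 3 of 3 libraries at 4 h. Gains were then first complete at the 4 times in 16.9%, 29.8%, 34.6% and 18.7% of regions, and losses in 14.3%, 44.7%, 25.4% and 15.6%. Leaving out each library gave gains of 843 to 2839, 1847 to 5626, 5518 to 9307 and 3072 to 8139, and losses of 357 to 1515, 1348 to 3275, 993 to 2333 and 1242 to 3089. Fisher's exact test called 0 regions under each alternative run. Unblocked, its smallest p was 0.0022 with all libraries and 0.011 without an untreated one, which leaves little power after adjustment. Trend calls were 2416 rising and 1364 falling with equal list length, 0 and 0 with 1 to 14 libraries per region, and 0 to 2627 and 0 to 401 without each library.

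For broad peaks the LPS ratio was 1.38 at 5 kb (exact permutation p = 0.242) and 1.79 with peaks within 1 kb joined (exact permutation p = 0.0527), against 3.27 at 20 kb (exact permutation p = 0.00879) and 2.69 to 4.14 without each library. Broad regions gained at the 4 times were 41, 56, 161 and 109 at 5 kb, 4, 6, 7 and 2 at 20 kb, and 31, 47, 103 and 64 after joining. Those lost were 7, 40, 23 and 17 at 5 kb, 0, 0, 1 and 0 at 20 kb, and 2, 11, 8 and 6 after joining. Without each library the gained were 15 to 28, 26 to 41, 43 to 49 and 24 to 47, and the lost 1 to 3, 2 to 6, 2 to 6 and 2 to 5. Depth is unknown, which limits every statement on a missing peak. Gene lists, motifs and position relative to genes were not run.

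Replicate numbers were also used as a replicate block, although the check gave no ground for pairing: same-numbered libraries correlated at 0.031 to 0.27. Over the count expected from swaps within numbers, gains were 3.19, 3.76, 6.18 and 4.71 times and losses 1.18, 2.69, 1.01 and 1.8 times, where the losses at 30 min were 0.877 times without the block. The blocked trend test called 0 rising and 0 falling regions. The blocked broad ratio was 3.37, and its sign-flip test cannot go below an exact p of 0.25.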

Other observations

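The descriptions of spacing and chromosomes, the splits of 6 libraries and the tests of broad peaks and of gains against losses were chosen after the results had been seen. The splits of 15 libraries and the test of the 4 h libraries were written down before theirs were.

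Changed regions lay closer to one another than random regions did, except for losses at 30 min. The p-values here come from draws of regions and measure no spread between libraries. Whether regions that differ between other splits of the libraries cluster as well was not tested. Of the regions gained at 1 h, 34.1% had another such region within 50 kb, against a mean of 14.4% for random regions found in the same number of libraries (permutation p = 0.001, one-sided, the smallest that 1000 draws can give). The shares were 12.1% against 6.79% at 30 min, 53.6% against 36.3% at 2 h and 43.3% against 22.5% at 4 h, with the same p. For losses the shares were 15.8% against 10.4% at 1 h, 13.4% against 7.29% at 2 h and 16.9% against 9.31% at 4 h (permutation p = 0.001 each), and 3.1% against 2.51% at 30 min (permutation p = 0.31). The densest 250 kb stretch, on chromosome 7 at 81500001 to 81750000, held 19 gained regions among 46. It includes the region at 81671686 to 81675861 that ranked first among the gains at 4 h. Next came chromosome 10 at 18750001 to 19000000 with 18 of 42 and chromosome 2 at 68750001 to 69000000 with 16 of 40.

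Gains were spread unevenly over chromosomes. On chromosome 2, 20.8% of testable regions were gained at 1 or more times against 17.3% elsewhere (Fisher's exact test, two-sided, adjusted p = 6.05e-05 over 42 tests), and on chromosome 16 the share was 20.4% (adjusted p = 0.037). By the same exact test it was lower on chromosome 9 with 13.9% (adjusted p = 0.000136), chromosome 8 with 14.3% (adjusted p = 0.0022) and chromosome 5 with 15.2% (adjusted p = 0.0177). Losses were fewer on chromosome 11, with 4.01% against 5.72% (Fisher's exact test, adjusted p = 0.00345). Neighbouring regions are not independent, so these p-values are too small.

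The rise in peaks of 10 kb or more after LPS was set against 2 technical explanations. The tables argue against longer lists: the 3 LPS libraries with fewer peaks than every untreated library still had at least 45 such peaks, above the untreated maximum of 37. If separate peaks joined across short gaps were the cause, joining peaks within 1 kb in every library would remove the difference; the ratio fell from 3.11 to 1.79 (exact permutation p = 0.0527), so this stays open. Sequencing depth and background are unknown and stay open, beside a biological widening of accessible chromatin after LPS.

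More regions were gained than lost at each time, and longer lists after LPS were tested as the reason. With lists of equal length gains still exceeded losses by 365, 255, 1299 and 899 regions at 30 min, 1 h, 2 h and 4 h, where the sides of any other split of the 6 libraries differed by at most 242, 197, 167 and 151. With the lists as deposited the excess was 496, 497, 4415 and 1809, so list length may account for part of it at each time. An excess remained at equal length, but 10 splits are too few for a share under 0.05. Whether the remainder goes beyond chance is therefore not shown. Leaving out a library loosens the rule in both directions. Without untreated replicate 1 more regions were lost than gained at 30 min (1515 against 843) and 1 h (3275 against 1847). The same held at 1 h without 1 h replicate 2 (2602 against 1852). Sequencing depth stays open, as does a net opening of chromatin by LPS.

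Fewer regions were gained at 4 h than at 2 h, a ratio of 0.555. With replicates 1 and 2 only, 8139 regions were gained at 4 h and 9307 at 2 h, a ratio of 0.875, but this leaves out replicate 3 at both times. With lists of equal length the ratio was 0.828, mainly because the 2 h count fell from 5272 to 3410, while the 4 h count went from 2928 to 2824. List length may therefore account for part of the drop, and whether through the short list of 4 h replicate 3 or the long lists at 2 h is not separated. A closing of regions between 2 h and 4 h stays open, untested.

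Other splits of the same libraries were counted. For 3 against 3 there are 10 splits, too few for a share under 0.05. At 30 min 2 of the 10 splits reached the real count of 1076, and the highest other gave 2419. At 1 h, 2 h and 4 h only the real split, 1 of 10, reached its count (3015, 6129 and 4047, against at most 2037, 1630 and 2335). In each case the highest other split set 3 short lists against 3 long ones, at 30 min with means of 58829 and 73858 peaks, so list length is a structure of these libraries. For broad regions only the real split, 1 of 10, reached its count at each time (16, 28, 45 and 25, against at most 1, 2, 2 and 3). Of 100 splits into 12 and 3, 4 reached the 2953 regions past an unadjusted Fisher exact p of 0.05, the real one and 3 that gave more. Those with 4026 and 3959 regions set 3 libraries with short lists apart (means of 54131 and 56265 peaks), and the one with 3323 set 3 with long lists apart (mean 81546). The share is under 0.05, but these splits by list length gave larger counts, and 0 regions passed adjustment. Of 100 orderings, 1 reached the 859 trend regions, the real one, and the highest other gave 0. That share is under 0.05 for these settings only. The count was also 0 with 1 to 14 libraries per region, with replicate numbers as blocks, and without 1 h replicate 1 or 4 h replicate 1. The orderings ignored replicate numbers. With a smallest Benjamini-Hochberg adjusted p of 0.0399 in the trend test, the real count itself stood close to the threshold.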
